A study of Drosophila melanogaster with 4 samples.

How the data were processed

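The samples were whole embryos of the Oregon-R strain. Per the labels' protocols, embryos not older than 16 h were fixed in 1.8% formaldehyde, and chromatin was incubated with the antibody for 15 hours and collected on beads. The labels name 2 ChIP samples made with an antibody to H3K79me3 and 2 input samples, each input being described as serving 1 of the ChIP experiments. All 4 samples share strain, stage and genotype, so the design holds no contrast between conditions. The comparisons are those between the 2 ChIP replicates, between the replicates and the series-wide list, and between chromosomes. The pairing of each input with its ChIP enters only through whatever the authors did to call regions.

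The authors deposited 1 list of regions for each ChIP replicate and 1 for the series. Bowtie 0.12.7 is named in the submitters' processing notes. The genome build is FlyBase r5, per the file headers. The region caller, its threshold, the read filters and the use of the inputs are not given in the sources used here, nor whether the series-wide list was made from pooled reads. Each row of the deposited lists gives a first and last base, a feature type (significant enrichment or depletion) and a score. The score is the authors' own value per region, its scale is not stated in the headers or labels, and it was used to describe, rank and filter regions within a list and to compare matched regions. It lay between 0.000283 and 3.41 for enriched regions. All coordinates of the series-wide list are even numbers, unlike those of the replicate lists, and 3 pairs of its regions share 1 base. The narrowest region has 1301 bp in both replicate lists and 1001 bp in the series-wide list. Regions called depleted (2 in replicate 1, none in replicate 2, 7 in the series-wide list) were left out of the comparisons of enriched regions and are described apart.

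Positions were used 1-based as deposited, and arm lengths were taken from the file headers. Gene positions for FlyBase r5 were not used here; the gene table at hand follows Release 6, and coordinates were not converted. The planned analyses of position relative to genes and of 23 gene lists fixed before the data were examined were therefore not run, and regions are named by position. The naming rule, also fixed before the data were examined, took the 10 highest-scoring and the 5 widest series-wide regions overlapped over at least 50% in both replicates, and the 5 widest regions of each replicate with no overlap in the other.

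A region counted as overlapped when at least 50% of its length lay inside regions of the other list. The observed share was compared with 1000 random placements, in which the regions of 1 list kept their widths and were placed without overlap on their own chromosome. The p-value is the share of placements at least as high, one-sided, with the observed value included. Matched pairs overlapped over at least 50% of both lengths. Coverage is the percent of a chromosome's length inside regions. Means over replicates are given with the SD and n = 2 and were not tested across samples, since the smallest exact two-sided sign-flip permutation p for 2 values is 0.5. Shares of regions carry 95% Wilson intervals, which cover counting error only, and since the lists hold no read counts, no depth-based limit could be set. The region lists were read as whole tables in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

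The overlap procedure was tested on simulated data with the number and widths of the replicate 1 regions (5938) and 200 placements. When 40.2% or 79.5% of the regions were copied to a second list with slightly shifted ends, 100% of the copied regions were recovered. The shifts were too small for any copy to fail the 50% rule, so this recovery was fixed in advance and checks only the computation. When none were copied, the placement permutation p was 0.164. Alternatives set before the data were examined were an overlap of 1 base or of 80%, the top 50% or 25% of each list by score, merging regions within 1 kb, restriction to the 5 large arms, lists of equal covered length, placement by circular shift, score divided by width, regions per Mb in place of bases, and each replicate alone. After the data were seen, 2 were added for the chromosome comparison: arms without the 1 Mb next to the centromere, and lists of equal covered length.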

Results

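H3K79me3, the trimethylated form of lysine 79 in the core of histone H3, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole embryos of the wild-type Drosophila melanogaster strain Oregon-R. In flies this mark is placed by the methyltransferase Grappa, the counterpart of Dot1, and it is known from transcribed genes. The embryos were labelled as 14 to 16 hr old, a late stage at which muscle, nervous system and epidermis differentiate. The labels describe 2 ChIP samples and 2 input samples, each numbered replicate 1 and 2. Region lists were analysed for the 2 ChIP replicates, together with 1 list that the authors deposited for the whole series; values of the input samples were not used here. The lists give each enriched region's position and a score. They hold no read counts, so the sequencing depth behind a region is unknown. The labels do not say that the replicates came from separate embryo collections, and the spread between them may be technical.

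The first comparison asked how much of the genome carried the mark and in what form. In the 2 replicates, 5938 and 5235 regions were called enriched, covering 32.3 Mb and 30.8 Mb. On the 5 large chromosome arms (2L, 2R, 3L, 3R and X) this came to 27.0% of the sequence in replicate 1 and 25.7% in replicate 2. Most regions were a few kilobases wide, with medians of 3295 bp and 3420 bp. Regions of 10 kb or more numbered 724 in replicate 1 and 742 in replicate 2. They made up 12.2% and 14.2% of the regions but held 42.0% and 46.7% of the covered bases. Wider regions had higher scores: across the regions of each list, which are not independent replicates, Spearman's rho between width and score was 0.80 in both replicates. The scale of the score is not named in the headers or labels, so scores are compared within it and not as folds.

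The second comparison asked whether the replicates marked the same places. Of the replicate 1 regions, 5148 (86.7%, 95% Wilson interval 85.8 to 87.5%) were overlapped over at least 50% of their length by replicate 2. Of the replicate 2 regions, 5014 (95.8%, 95.2 to 96.3%) were overlapped in this way by replicate 1. Random placement of the regions within each chromosome gave means of 25.4% and 26.7%, and no placement reached the observed shares. The one-sided placement permutation p was 0.000999 in both directions, the smallest that 1000 placements can give; it compares these 2 libraries and not embryos in general. The replicates shared 29.5 Mb, which is 87.8% of the 33.6 Mb covered by either. The intervals cover counting error only.

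Every one of the 724 and 742 regions of 10 kb or more was overlapped over at least 50% of its length in the other replicate. Differences were concentrated in narrow, low-scoring regions. Among regions under 2 kb, 52.4% of those in replicate 1 and 83.2% of those in replicate 2 were overlapped. In replicate 1, 706 regions shared no base with replicate 2; their median width was 1591 bp and their median score 0.471, against 3766 bp and 1.01 for the overlapped regions. In replicate 2, 190 regions shared no base with replicate 1, with a median width of 1578 bp and a median score of 0.496, against 3586 bp and 0.966. The widest region found in replicate 1 alone lay on 2L from 935205 to 940457 (5253 bp, score 0.682). The next lay on 2R from 20872757 to 20877833, on 3R from 27724985 to 27729433, on 3L from 17135473 to 17139698 and on 3R from 27377160 to 27381196. In replicate 2 alone, the widest lay on 2L from 6109418 to 6112962 (3545 bp, score 0.452) and from 21750320 to 21753714. They were followed by chromosome 4 from 376658 to 380001, 3R from 13661597 to 13664871 and 3L from 15914523 to 15917604. Each of these 10 regions was covered over 79.9% or more of its length by the series-wide list.

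**Figure D1:**
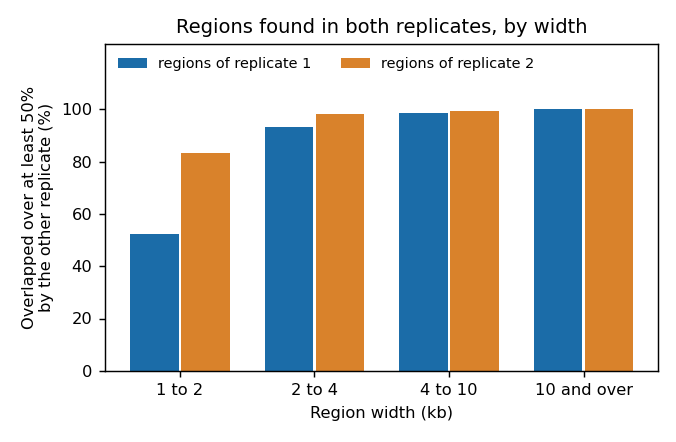
The bars give the share of regions (percent) of each replicate that were overlapped over at least 50% of their length by the other replicate, by region width in kb. The share was 52.4% and 83.2% for regions under 2 kb and 100% in both replicates for regions of 10 kb or more.

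Scores and widths were also compared at matched places. Regions that overlapped each other over at least 50% of both lengths formed 4581 pairs. Across these pairs, Pearson's r was 0.97 and Spearman's rho 0.96 for the score, and 0.97 and 0.95 for the width. Pairs are not independent replicates, and pairing required similar widths, so the width correlations are high in part by construction. On the 5 large arms the median score difference, replicate 2 minus replicate 1, was -0.0358, and 1765 of 4539 pairs (38.9%) were higher in replicate 2. Chromosome 4, the small chromosome that is largely packaged as heterochromatin, went the other way. There the median difference was 0.127 in favour of replicate 2, 18 of 25 pairs were higher in it, and matched regions were 1.21 times as wide at the median. In 10000 draws of pairs from the 5 large arms, matched to the chromosome 4 pairs on their replicate 1 score, the median difference never exceeded 0.106. The draws took pairs singly from across the arms, so they do not show how far the median of a contiguous stretch can move. This comparison was chosen after the data were seen and describes these 2 libraries.

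**Figure D2:**
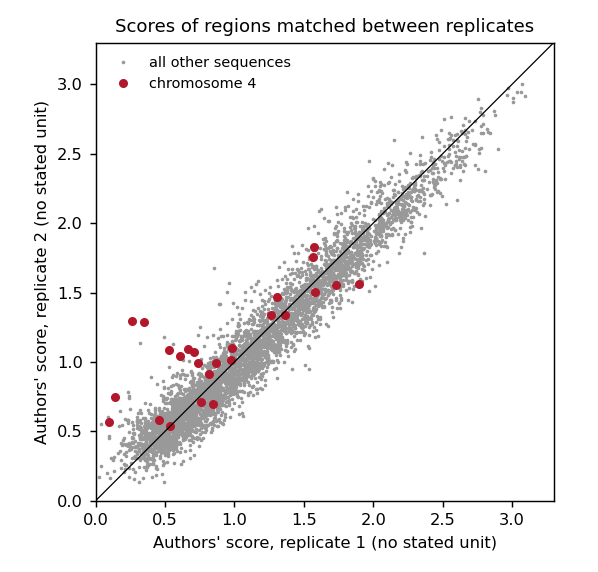
Each point is a pair of regions matched between the replicates, with the authors' score in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis (no stated unit); the line marks equal scores. The 25 pairs on chromosome 4 are drawn larger, and 18 of them lie above the line.

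The strongest and the broadest marked places were named by a rule fixed before the data were examined. Among series-wide regions present in both replicates, ranked by the series-wide score, the highest belonged to a region on 3R from 11067750 to 11072834 (5085 bp). Its score was 3.01 in the series-wide list and 3.01 ± 0.125 (SD, n = 2) in the replicates. It was followed by 2R from 8802768 to 8812740 with 3.01 ± 0.0863 in the replicates, and by X from 1832278 to 1849940 with 2.99 ± 0.0624. The other 7 of the 10 highest lay on 3R from 1305564 to 1310456, from 27423422 to 27441038, from 22972794 to 22978228 and from 12067770 to 12086288, and on 2R from 4501386 to 4511736, from 18685738 to 18690360 and from 13344260 to 13353030. Of the 10, 5 were on 3R, 4 on 2R and 1 on X, and the last of them scored 2.83 in the series-wide list. Ranked by the mean of the replicates, the first of these 10 was the region on 3R from 22972794 to 22978228, with 3.04 ± 0.0485 against 2.89 in the series-wide list. They were 4623 to 18519 bp wide.

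The broadest region covered 116639 bp on 3R from 5697924 to 5814562. It was a single region of 116535 bp in replicate 2, while replicate 1 split it into 3 regions that together covered 98.9% of it. A region of 106369 bp on 3L from 22295352 to 22401720 was continuous in both replicates, at 106340 and 106252 bp, with a mean score of 2.37 ± 0.118 (SD, n = 2). The next were 2R from 6914554 to 6995136 (80583 bp), 3R from 10233650 to 10309838 (76189 bp) and 3L from 22127910 to 22203116 (75207 bp). Replicate 2 split the last of these into 2 regions. All positions are 1-based on FlyBase r5. Genes under these regions were not assigned, because the gene table used here follows another release.

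The third comparison asked how the mark was distributed over the chromosomes. Coverage was highest on 2R, at 29.9% ± 1.33 (SD, n = 2), and lowest among the large arms on 2L, at 23.9% ± 0.749. The arms 3L, 3R and X had 26.5% ± 0.852, 26.5% ± 1.10 and 25.2% ± 0.776. In both replicates 2R ranked first and 2L last. Chromosome 4 had 9.44% ± 2.70, which was 0.357 ± 0.115 of the level on the 4 large autosomal arms together; counted as regions per Mb the ratio was 0.627 (0.539 and 0.714 in the 2 replicates). The 6 heterochromatin sequences (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, 9.28 Mb in all) held 13 and 20 regions and had 0.397% ± 0.107 of their length covered. Sequence that takes up no reads would also look uncovered, here and on chromosome 4, and this was not tested. These ratios were not tested across samples, since an exact two-sided sign-flip permutation of 2 values gives no p below 0.5.

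The X was covered slightly less than the 4 autosomal arms together in both replicates, at 25.8% against 27.3% in replicate 1 and 24.7% against 25.9% in replicate 2. It lay within the range of the single autosomal arms, since 2L had 24.4% and 23.4%. The ratio was 0.947 ± 0.00663 (SD, n = 2), an SD that leaves out the spread between arms. The number of regions per Mb on X was 1.00 and 0.988 times that on the autosomal arms. X regions were narrower at the median, at 3197 bp against 3358 bp in replicate 1 and 3387 bp against 3480 bp in replicate 2, but wider in the series-wide list, at 3343 bp against 3290 bp. In the replicates they had higher scores, with medians of 0.946 against 0.865 and 0.966 against 0.920. Whether read depth on the X affected its coverage or scores was not tested.

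On chromosome 4 the replicates differed by more than on any large arm. Coverage was 7.53% in replicate 1 and 11.4% in replicate 2, a ratio of 1.51, whereas each of the 5 large arms had a ratio of replicate 2 to replicate 1 between 0.939 and 0.957. The 6 Het sequences together also rose, from 0.321% to 0.473%, a ratio of 1.47 on 13 and 20 regions. The number of chromosome 4 regions was 36 and 42. The widest had 7846 bp in replicate 1 and 17485 bp in replicate 2. The latter was the only chromosome 4 region of 10 kb or more in either replicate. How much of the difference it made up was not examined. The shared bases of chromosome 4 were 65.6% of the union of both replicates, against 87.1 to 88.7% on the large arms.

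**Figure D3:**
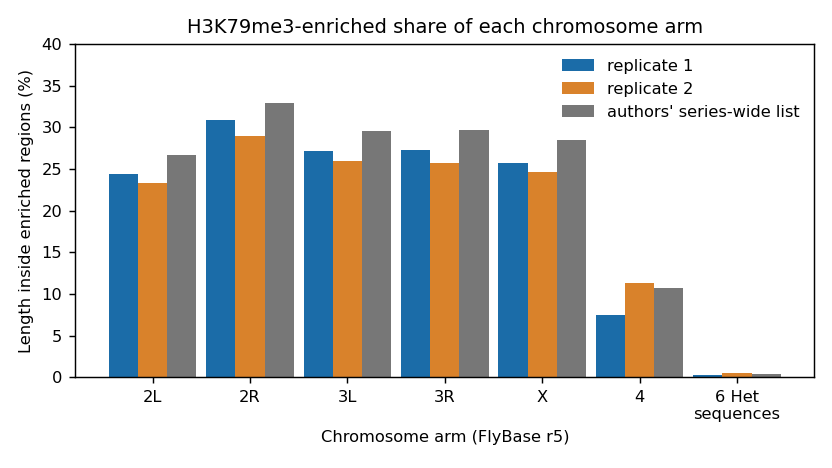
Bars give the share of each chromosome arm (percent of its FlyBase r5 length) inside enriched regions for replicate 1, replicate 2 and the authors' series-wide list. The 5 large arms lie between 23.4% and 33.0%, chromosome 4 between 7.53% and 11.4%, and the 6 Het sequences together at most 0.473%.

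Along the large arms, coverage was read in bins of 1 Mb, a division made after the data were seen. Over 117 full bins the median was 27.3%, and the replicates followed each other closely (Pearson's r 0.99 across bins). The densest bin lay on 3R from 5 to 6 Mb, with 49.1% ± 0.428 (SD, n = 2) covered, and contained the broadest region named above. It was followed by the first bin of 3L with 42.0% ± 1.87 and by 2R from 6 to 7 Mb with 41.6% ± 1.43. The sparsest bins were the full bins nearest the centromeres of 3L, 2R and 2L, at 1.01% ± 0.620, 2.47% ± 0.913 and 4.00% ± 0.196. Whether reads could be placed on these stretches as well as elsewhere was not tested. The final 1 Mb beside the centromere on X was covered to 6.90% and 7.42% in the 2 replicates. On 3R the same stretch had 28.7% and 26.1%, close to the whole arm's 27.2% and 25.7%. Sparse bins also lay within arms, on 2L from 15 to 16 Mb with 6.27% ± 0.215 and on 3R from 3 to 4 Mb with 10.4% ± 0.404.

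**Figure D4:**
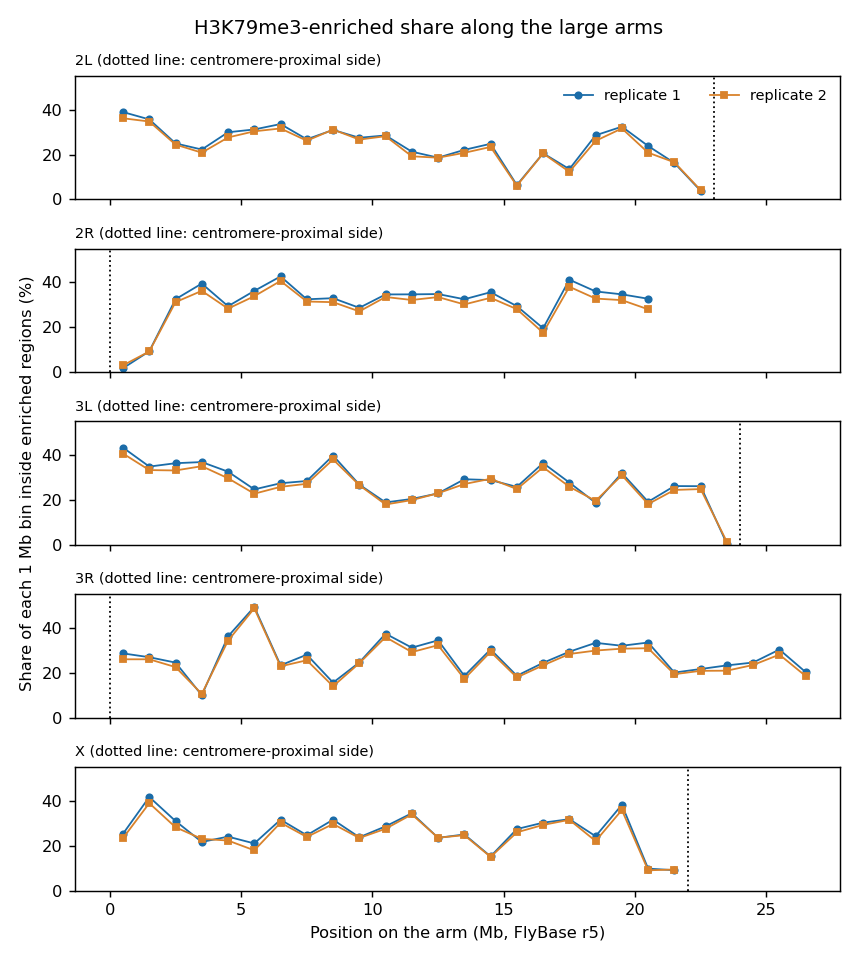
Lines give the share (percent) of each full 1 Mb bin inside enriched regions along the arms 2L, 2R, 3L, 3R and X for both replicates; the horizontal axis is the position in Mb and the dotted line marks the side nearest the centromere. In the full bin nearest the centromere, mean coverage falls to 4.00% on 2L, 2.47% on 2R, 1.01% on 3L and 9.31% on X, and not on 3R.

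The last comparison set the authors' series-wide list beside the replicates. It held 6152 enriched regions over 35.2 Mb, more than either replicate. Of these, 4506 (73.2%, 95% Wilson interval 72.1 to 74.3%) were overlapped over at least 50% of their length in both replicates, 706 (11.5%) in replicate 1 only and 183 (2.97%) in replicate 2 only. The remaining 757 (12.3%) were not overlapped to that extent in either, and 729 shared no base with any replicate region. In the other direction, 99.6% of the regions of each replicate were overlapped by the series-wide list. Series-wide regions present in both replicates were 4392 bp wide at the median with a median score of 0.996, against 1251 bp and 0.341 for those in neither. Of the 757, 420 were narrower than 1301 bp, the narrowest region of either replicate list, while the series-wide list went down to 1001 bp.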

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

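The tests on chromosome 4, on the sign of scores and on the width of X regions were chosen only after the result was seen. The series-wide list holds 7 regions called depleted, from 1465 to 1845 bp wide, a signal outside the comparisons of enriched regions.

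Of these 7 depleted regions, 4 lay over at least 50% of their length under a region called enriched in a replicate, with replicate scores from 0.0896 to 0.226. One of them, on 3L from 16573126 to 16574786 (score -0.00044), was covered to 94.1% and 90.4% by enriched regions with scores of 0.105 and 0.162 in the replicates. A further one, on 2R from 14034350 to 14035974, was also called depleted in replicate 1, outside the 4. No region among the 17334 of the 3 lists had a name against the sign of its score (0 regions), and the highest depleted and lowest enriched scores of the series-wide list were -0.00044 and 0.000283. A name given by the sign of a score near 0 is not excluded by these values. Whether H3K79me3 lay below background at any of the 7 was not tested and stays open; replicate 2 has no region called depleted.

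Chromosome 4 was covered 1.51 times as much in replicate 2 as in replicate 1, while the 5 large arms went the other way. Chromosome 4 regions matched between the replicates scored 0.127 higher in replicate 2 at the median. The highest of 10000 draws from the large arms matched on replicate 1 score was 0.106. The draws took pairs singly from all 5 large arms, whereas the chromosome 4 pairs lie on a single short sequence. Such draws cannot show how far the median of a contiguous stretch moves between libraries. No conclusion on a more permissive list for replicate 2 is drawn from them. Of 86 consecutive windows of the same length on the large arms, 1 had a ratio as high. Chromosome 4 was singled out because it differed, so this count cannot decide on variation between stretches of this length. That window and the 2 next highest (ratios 2.89, 1.49 and 1.10) lay nearest the centromeres of 3L, 2R and 2L, where replicate 1 covered 0.420%, 2.17% and 4.92%. In the 8 windows with 0.5 to 2 times the mean coverage of chromosome 4, the ratio ran from 0.902 to 1.10 against its 1.51. These few windows were chosen after the data were seen, and no conclusion on variation between stretches of similar coverage is drawn from them. They leave out the windows with ratios of 2.89 and 1.49, so sparser stretches near the centromeres were not part of this comparison. A difference in heterochromatin, in the inputs or in the embryos may be shared with the Het sequences. Their covered share rose from 0.321% in replicate 1 to 0.473% in replicate 2, a ratio of 1.47 beside the 1.51 of chromosome 4. Their 13 and 20 regions were too few to decide (two-sided exact binomial p = 0.119). XHet fell, from 3 regions to 2, where the others did not.

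Regions on the X had higher scores than those on the autosomal arms. Matching on width could hardly lower this excess in the replicates, since X regions were narrower at the median and wider regions scored higher. At matched width the X excess in median score was 0.0786 (0.103 and 0.0540 in the 2 replicates), beside 0.0811 and 0.0454 before matching. No conclusion on width is drawn from the replicates. In the series-wide list, where X regions were wider at the median, matching moved the excess from 0.0850 to 0.0800. In the mean of the replicates, no autosomal arm differed from the other 3 by more than 0.0174. Only 4 autosomal arms were compared, so no conclusion on variation between arms is drawn from that mean. That mean lets opposite signs cancel: 3R differed by -0.00957 in replicate 1 and by 0.0320 in replicate 2, where the X excess was 0.0540. In the series-wide list 3L and 3R differed by -0.0347 and 0.0306, against 0.0800 for X. The X excess was 0.0845 and 0.0846 among regions under 2 kb and 0.0151 and -0.0106 among those of 10 kb or more. The number of X copies in embryos of both sexes, which would lower the X reads of the input and the ChIP alike, was not tested and stays open. Since the lists hold no read counts, whether fewer X reads changed which X regions were called could not be checked. A biological difference of the X also stays open.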

How the results depend on the processing

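For the chromosomes, equal covered length and leaving out the 1 Mb next to the centromere were chosen only after the result was seen. The overlap between replicates stayed above all random placements under every alternative run. The share of replicate 1 regions overlapped ranged from 78.1% (overlap of at least 80%) to 91.9% (equal covered length), that of replicate 2 regions from 86.9% (equal covered length) to 96.6% (top 50% by score), and the shared bases from 81.1% (top 25% by score) to 88.3% of the union (regions merged within 1 kb). The share of series-wide regions overlapped in both replicates moved from 73.2% to 75.1% with any overlap, 59.0% with at least 80%, 79.4% and 78.7% in the top 50% and 25% by score, and 76.7% with regions merged within 1 kb. The share in neither replicate moved from 12.3% to 17.9% with at least 80%, 8.49% and 6.05% in the top 50% and 25%, and 10.2% with merging. Judged by 1 replicate alone, the overlapped share ranged from 76.2% to 84.7% and the rest from 15.3% to 23.8%, by construction, since only 1 list then has to match. Pairs overlapping over at least 80% of both lengths had Pearson's r of 0.98 and Spearman's rho of 0.97 for the score and 1.00 and 0.99 for the width. The stricter overlap keeps only pairs of closer widths, so the rise for the width is in part by construction. The score divided by width gave 0.90 and 0.87. The cause of the changes for the score was not tested. The X ratio kept below 1 in the mean of the replicates but moved from 0.947 to 0.982 in the top 50% by score, 0.997 for regions per Mb (1.00 in replicate 1) and 0.960 at equal covered length; the cause was not tested. Chromosome 4 relative to the autosomal arms moved from 0.357 to 0.627 when regions per Mb replaced bases, and its ratio between replicates from 1.51 to 2.22 in the top 50% by score, to 1.85 at equal covered length, which shortened only the replicate 1 list and so could not lower it, and to 1.17 for regions per Mb. Without replicate 1 chromosome 4 stood at 0.438 of the autosomal level and without replicate 2 at 0.275. The other alternatives left the X and chromosome 4 relative to the autosomal arms within the spread between replicates, which leaving out 1 of 2 replicates cannot exceed. For the 15 named regions present in both replicates, 15 values stayed and 5 moved under merging or, for the widest, the filter on score, the largest from 96.2% to 91.6% covered on 3L from 22127910 to 22203116. Merging left the 10 regions named in 1 replicate at 0% in the other, and the filter on score cannot change them. No paired analysis was possible because the groups that share replicate numbers are ChIP and input, and values of the input samples were not used here. Settings for gene lists, gene position and gene-containing length were not run, since they need gene positions on FlyBase r5. The lists hold no read counts, so whether narrow, low-scoring regions of 1 replicate were missed for lack of depth in the other cannot be settled from them.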

Other observations

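All comparisons in this part were chosen only after the result was seen. Long stretches without a called region were sought in both replicate lists joined together, so each is empty in both by construction. Sequence that takes up no reads would look the same and was not tested. On 3L a stretch of 433 kb from 18179351 to 18612616 held no enriched region in either replicate, and 0.0132% of it was covered in the series-wide list. The final 520 kb of 3L, beside the centromere, were also free of regions in all 3 lists. Within 2L, 353 kb from 17777813 to 18131285, 304 kb from 14689996 to 14993951 and 299 kb from 16902441 to 17201737 were free of regions in both replicates. On X, 344 kb from 21501918 to 21845866 were free, on 3R 309 kb from 6719732 to 7028271, and on 2R 259 kb from 718438 to 977726. The series-wide list covered 0.401% of the stretch on 3R, 0.0845% of that on 2R and at most 0.0132% of the others. The stretch on 3R lies 905 kb beyond the end of the broadest enriched region of the series.

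The matched pairs on chromosome 4 were also divided by their replicate 1 score, which is itself a term of the difference. For the 17 matched pairs with a replicate 1 score under 1, the median score was 0.252 higher in replicate 2 and 14 were higher. For the 8 pairs with a score of 1 or more, the median difference was 0.0265 and 4 were higher. Draws from the large arms matched on score gave 95% ranges of -0.0754 to 0.0664 and -0.161 to 0.0493 for sets of these sizes. These draws also took pairs singly from across the arms. The difference between the 2 sets was not tested.

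Among the 729 series-wide regions that shared no base with either replicate, with a median score of 0.341, the 5 highest scores were 3.41, 2.86, 1.44, 1.44 and 1.37. The first, the highest of the list, lay on 3L from 9571272 to 9572282 (1011 bp) and the second on 2R from 9024432 to 9025432 (1001 bp). The others lay on 3L from 2455662 to 2456696, on U from 9711602 to 9712814 and on 3R from 4697470 to 4698470. All 5 are narrower than any region of the replicate lists.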
